A study of Homo sapiens with 18 samples.

How the data were processed

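RNA of the U87MG glioblastoma line was measured by sequencing in 18 libraries, from 3 control and 3 radioresistant biological replicates with 3 technical replicates each. Per the labels, total RNA was extracted with Trizol, libraries were made with a strand-specific kit, and reads were aligned with TopHat to hg19. The quantification tool and the annotation are not given in the sources used here. The deposited files name no unit. As deposited by the authors, the values were scaled by transcript length and library size and were read here as FPKM. This was inferred from their steps in genes with few fragments and from sums that differ between libraries. The scaling between libraries is not stated. Sums ran from 249012 to 258502 FPKM in control replicate 1 and from 568327 to 964848 FPKM in the other libraries. The files hold no counts, so depth was estimated from the smallest steps of the values in genes with a single transcript of 800 to 6000 bases, using the lowest 12% of the products of value and length, a share chosen after the data were seen and tested on simulated data. No counting interval can be given.

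Identical values in technical replicates 1 and 2 of radioresistant replicate 2 were counted once. Technical replicates were averaged as log2(FPKM + 1), and genes with a mean of at least 1 FPKM over the replicates tested were kept. Groups were compared with limma 3.58.1 in R 4.3.3 (eBayes with trend and robust options, two-sided), without covariates, at a Benjamini-Hochberg adjusted p under 0.05. A count-based test had been planned first, with this test named for normalized values. Genes of 34 lists, named in the report, were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, where at least 5 members were tested; chromosomes were tested in the same way. For chromosomes, transcript length and GC content, names were matched to RefSeq genes of GRCh38, 21717 by symbol and 1624 by synonym of 24424, and 1083 by none. Replicates of a group were compared with limma with the technical replicates as residual. The tests, lists, naming rule and main alternatives were chosen before the data were examined.

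Genes were named by rule: the 10 largest increases and decreases among genes past the threshold with a mean of at least 5 FPKM and groups that did not overlap, the 3 smallest p-values in each direction, up to 4 members of each list with the smallest p, and a fixed set that held CDKN1A, MDM2, CDKN2A, EGFR, MGMT, PROM1, CD44 and SOX2. Some genes that the rule takes are not reported here. Genes without an official symbol and small, antisense or pseudogene RNAs were passed over. Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, each replicate left out, the replicate number as a block, each technical replicate alone, technical replicates as separate libraries with a common correlation, an adjusted p under 0.01 and a test against a fold change of 1.5. Median-of-ratios scaling over genes with at least 1 FPKM in every replicate, quantile normalization, removal of trends with transcript length and GC content (lowess, span 0.3) and the full comparison without control replicate 1 were added after the data were seen. In that comparison radioresistant replicate 1 has no control of its number. The block then takes its differences from replicates 2 and 3 of each group alone and leaves little to estimate the spread. Alternatives that need counts were not run. Recovery was tested on simulated data with the spread of the replicates.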

Results

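U87MG is an established human glioblastoma cell line, used here in a derivative that expresses luciferase. RNA was profiled by sequencing in 2 groups of cells. Control cells had not been irradiated. Radioresistant cells had been grown under the skin or in the brain of nude mice, and irradiated in fractions of 2 Gy to a total of 30 Gy, and the surviving cells had been recovered. Each group held 3 biological replicates and each of these had 3 technical replicates, which gave 18 libraries. The labels do not say whether the control cells had passed through mice, nor at which site each radioresistant replicate had grown. The labels do not say that the biological replicates came from separate cultures or animals, so a p-value measures the spread between these samples. The unit is not named in the files, and the values were read as FPKM (fragments mapped to a gene, scaled by transcript length and library size), for 24424 genes. The files of technical replicates 1 and 2 of radioresistant replicate 2 held identical values and were counted as 1 library, so that 17 distinct libraries remained.

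Control replicate 1 differed from all other replicates in depth and in content. The size of the smallest steps in the values put the 3 libraries of this replicate at about 739000 to 877000 fragments, and the other libraries at about 14700000 to 22200000 fragments. On log2(FPKM + 1), its correlation with each of the other 5 replicates was between 0.207 and 0.227 across genes, whereas control replicates 2 and 3 correlated at 0.998. VIM, the mesenchymal intermediate filament gene, was listed at 29.5 FPKM in control replicate 1 and at no less than 2337 FPKM in any library of the other replicates. CDKN2A and MTAP, neighbouring genes whose loss is a known feature of U87MG, were listed at 47.5 and 6.47 FPKM in control replicate 1. In the other replicates no library listed CDKN2A above 0.249 FPKM or MTAP above 0.052 FPKM. HBB (a globin gene), PTPRC (the leukocyte antigen CD45) and LYZ (lysozyme) were listed at 337, 37.8 and 54.7 FPKM in control replicate 1, and at no more than 3.63, 0.0475 and 0.91 FPKM in any other library. These genes were chosen after their values were seen. RPLP1, a ribosomal protein gene, was listed at 0 in all 3 libraries of control replicate 1 and at 3330.5 FPKM or more elsewhere, so a value of 0 in these files can be a failed estimate.

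**Figure D1:**
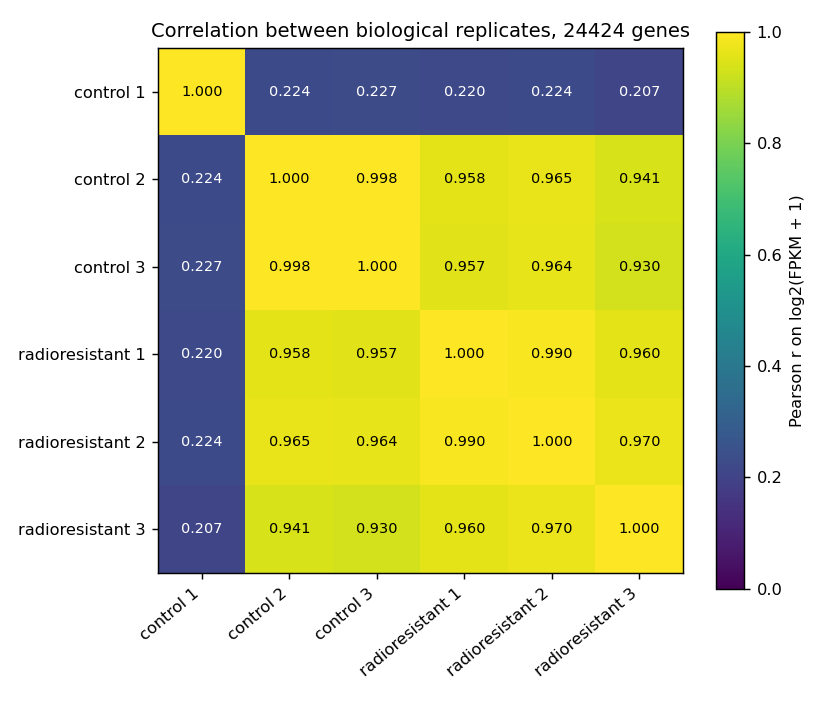
Pearson correlation between the 6 biological replicates on log2(FPKM + 1) over all 24424 genes, with technical replicates averaged; colour runs from 0 to 1. Control replicate 1 sits between 0.207 and 0.227 against every other replicate, and the other pairs sit between 0.930 and 0.998.

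The comparison asked which genes differ in expression between the radioresistant cells and the non-irradiated cells of the same line. With all 6 biological replicates, 6 genes rose in the radioresistant cells and no gene fell, among 15626 genes tested with limma. The 6 were CGB (chorionic gonadotropin beta), LCN2 (the iron-carrier protein lipocalin 2), CXCL5 (a neutrophil-attracting chemokine), EFNA1 (an ephrin ligand), G0S2 (an inhibitor of triglyceride breakdown) and C19orf33. CXCL5 was at 0.477, 0.0536 and 0.127 FPKM in control replicates 1, 2 and 3 and at 243 ± 150.4 FPKM (SD, n = 3) in the radioresistant replicates, a difference of 7.49 ± 0.62 (SE) on the log2(FPKM + 1) scale (adjusted p = 0.0327). LCN2 was at 0, 0.14 and 0.0953 FPKM in the controls and at 50.8 ± 18 FPKM (SD, n = 3) in the radioresistant cells (adjusted p = 0.0327). EFNA1 was at 0, 0.0785 and 0.0837 FPKM against 25.2 ± 6.59 FPKM (SD, n = 3; adjusted p = 0.0409). The lower genes with the smallest p-values were TIMP3, an inhibitor of matrix proteases, ADCY8, an adenylate cyclase, and LAMA4, a laminin chain, with adjusted p-values of 0.0696, 0.0822 and 0.0822. At an unadjusted p under 0.05 there were 883 genes, and the groups did not overlap for 26% of genes. Chance gives 10% if all replicates vary alike, which control replicate 1 did not. In data simulated with the spread of these 6 replicates and 15626 genes, the test recovered 0% of genes changed by 4 on the log2 scale. The changed genes had a control mean above 3 on that scale. Without control replicate 2, control replicate 3 or any 1 radioresistant replicate the count was 0, and without control replicate 1 it was 1224.

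Leaving out control replicate 1 was 1 of the alternatives fixed before the data were examined, and describing its result in full was chosen after the data were seen. With this replicate left out, 656 genes rose and 568 fell among 11960 tested, and 1131 of the 1224 changed at least 2-fold. All 6 genes named above were among them. With all 6 replicates, 1207 of these genes were tested by limma, and 1141 had the same direction and 66 the opposite. An unadjusted p under 0.05 was reached there by 609. The comparisons that follow set radioresistant replicates 1 to 3 against control replicates 2 and 3, and values are means ± SD with n = 2 for control and n = 3 for radioresistant cells. Among the largest increases were RARRES2, which encodes the chemoattractant chemerin and rose from 0.16 ± 0.0689 to 584 ± 699 FPKM (adjusted p = 0.011), IL32, a cytokine gene, from 0.307 ± 0.0643 to 248 ± 105 FPKM (adjusted p = 8.34e-04), and G0S2, from 1.6 ± 0.436 to 403 ± 194 FPKM (adjusted p = 8.34e-04). S100A4, a calcium-binding protein linked to cell motility, rose from 39.9 ± 9.6 to 2875 ± 2484 FPKM, INHBA, the activin A subunit, from 0.106 ± 0.0159 to 56.4 ± 21.7 FPKM, and BST2, the antiviral protein tetherin, from 1.72 ± 0.823 to 168 ± 163 FPKM. RARRES2 varied between the radioresistant replicates, at 73.3, 298 and 1381 FPKM. CXCL3, CXCL5, C19orf33 and CGB completed the 10 largest increases among genes with an official symbol and a mean of at least 5 FPKM. The log2 differences of CXCL3, CXCL5 and CGB were 6.33, 7.62 and 6.17, and C19orf33 was at 0.651 and 0 FPKM in control replicates 2 and 3 and at 121, 78.9 and 337 FPKM in the radioresistant replicates. CGB belongs to a cluster of near-identical gonadotropin genes, so its value is uncertain where reads could be split among them. CT55, a cancer-testis gene with 1 of the 3 smallest p-values among increases, rose from 0.142 ± 0.0915 to 12.8 ± 0.671 FPKM (adjusted p = 8.34e-04).

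Among the 10 largest decreases were NDP, which encodes the Wnt receptor ligand norrin and fell from 82.6 ± 2.34 to 1.09 ± 0.148 FPKM (adjusted p = 6.62e-04), and CDR1, from 50.7 ± 0.548 to 0.335 ± 0.119 FPKM (adjusted p = 6.62e-04). HMGN3, a nucleosome-binding protein gene, was at 25.8 and 26.1 FPKM in control replicates 2 and 3 and was listed at 0 in all radioresistant replicates (adjusted p = 6.62e-04). As with RPLP1, a value of 0 can be a failed estimate, so this decrease is uncertain. VAT1L, CAMK2N1 (an inhibitor of the kinase CaMKII), TIMP3, SPOCK3 (a matrix proteoglycan), LAMA4 and HGF (the ligand of the receptor MET) were also among the 10, with log2 differences of -4.87, -4.52, -4.34, -4.29, -4.00 and -3.95. The remaining gene was DKK1, a secreted Wnt inhibitor, and its values are given with the Wnt pathway. HGF fell from 23.8 ± 1.48 to 0.608 ± 0.0481 FPKM. These 20 genes were taken among genes whose groups did not overlap. Of all genes tested, 53.2% had groups that did not overlap, where chance gives 20% if all replicates vary alike. Control replicates 2 and 3 lay closer together than the radioresistant replicates (r = 0.998 against 0.960 to 0.990). This raises the share without any group effect, so the 20% is too low a mark here. In simulated data with this spread and 11960 genes, 10% of genes changed by 1 on the log2 scale were recovered, 78% of those changed by 2 and 100% of those changed by 3. The changed genes had a control mean above 3 on that scale, so the rates do not cover genes near 0 in the controls. Of the unchanged genes, 7 were called. The count rests on few replicates: it was 256 without control replicate 3, 269 without control replicate 2, 490 without radioresistant replicate 2, 628 without radioresistant replicate 1 and 4286 without radioresistant replicate 3.

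**Figure D2:**
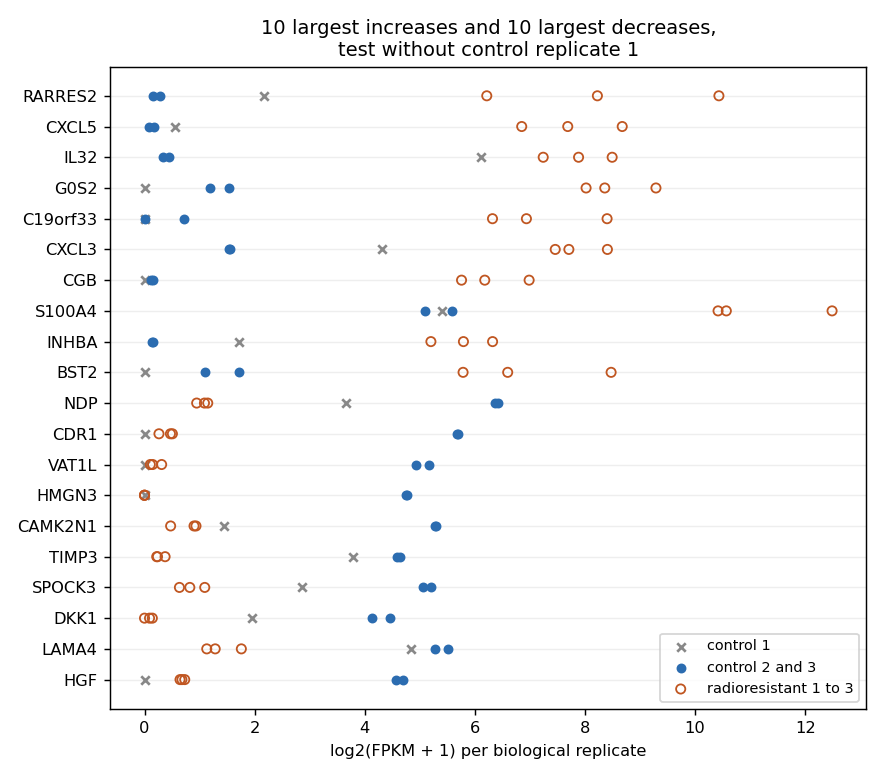
Expression of the 10 genes with the largest increase and the 10 with the largest decrease in each biological replicate, on a log2(FPKM + 1) axis; filled points are control replicates 2 and 3, open circles the radioresistant replicates, and crosses control replicate 1, which was not used in this test. The genes were taken among those whose groups did not overlap, and among the increases RARRES2 runs from 73.3 to 1381 FPKM in the radioresistant replicates.

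Of the 26 tested members of the list of NF-kB targets and inflammatory cytokines, 17 rose and none fell (21 higher and 0 lower adjusted over the list alone), with a median log2 difference of 2.41. IL32 and CXCL3 rose as given above. CXCL2, a neutrophil-attracting chemokine, rose from 2.35 ± 0.319 to 135 ± 26.7 FPKM and ICAM1, an adhesion molecule for leukocytes, from 3.78 ± 0.0214 to 84.4 ± 18.6 FPKM (adjusted p = 8.34e-04 and 0.00104). The list stood above other genes by camera with a preset correlation (adjusted p = 1.95e-14) but not with an estimated correlation (adjusted p = 0.0911). With all 6 replicates its median was 3.33 (adjusted p = 1.37e-14; adjusted p = 0.0977 with an estimated correlation). No other list reached an adjusted p below 0.0911 with an estimated correlation, and none of the 32 lists tested passed 0.05 in that test. The estimated correlations of the NF-kB, interferon and stem-like lists were -0.017, -0.022 and -0.065, below the preset 0.01. Correlation between their genes thus did not end these calls. For HOX, cancer-testis, hypoxia and matrix protease genes the estimates were 0.145, 0.216, 0.083 and 0.131. For matrix glycoprotein, histone, ribosomal protein and receptor tyrosine kinase genes they were 0.336, 0.363, 0.518 and 0.047. All of these lie above 0.01, so p-values with the preset correlation can be too small for these lists. Notch and Wnt genes and cholesterol genes, at 0.0061 and -0.031, lay below it. The test with an estimated correlation has few degrees of freedom with these replicates, so a list that fails it is not shown to be unchanged.

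Of 26 interferon-stimulated genes tested, 6 rose and none fell (7 higher and 2 lower adjusted over the list alone), and the median log2 difference was 0.72. IFI27 rose from 0.568 ± 0.0211 to 6.38 ± 1.28 FPKM, XAF1, a pro-apoptotic interferon target, from 0.236 ± 0.00706 to 2.3 ± 0.317 FPKM, and IFITM1, which restricts viral entry, from 0.222 ± 0.0467 to 2.13 ± 0.804 FPKM. BST2 rose as given above. The list passed by camera (adjusted p = 0.016; adjusted p = 0.308 with an estimated correlation), and not without radioresistant replicate 2 (adjusted p = 0.0586) or with a mean of at least 5 FPKM (adjusted p = 0.0721); over its alternatives the adjusted p ran from 0.00502 to 0.0721. Of 16 genes of MHC class I antigen presentation, 1 rose, namely ERAP2, a peptide-trimming aminopeptidase, from 17.4 ± 1.66 to 42.9 ± 8.13 FPKM (adjusted p = 0.0415; 0 higher and 0 lower adjusted over the list alone). The immunoproteasome genes PSMB10 and PSMB9 and the gene HLA-F had log2 differences of 1.49 ± 0.40, 1.15 ± 0.47 and 0.68 ± 0.34 (SE) and did not pass. The list did not pass (median 0.51; adjusted p = 0.0896 by camera; adjusted p = 0.635 with an estimated correlation). It passed by camera with a preset correlation when all 6 replicates were used, where its median was 1.31 (adjusted p = 0.00811 by camera and 0.847 with an estimated correlation).

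Of 34 genes of hypoxia and glycolysis tested, 8 rose and 2 fell (12 higher and 2 lower adjusted over the list alone). CA9, the cell-surface carbonic anhydrase and a target of hypoxia-inducible factor, rose from 9.41 ± 0.386 to 326 ± 24 FPKM (adjusted p = 8.34e-04). EGLN3, an oxygen-sensing prolyl hydroxylase, rose from 0.199 ± 0.0257 to 13.1 ± 2.15 FPKM, ALDOC, a glycolytic aldolase, from 6.56 ± 0.24 to 104 ± 22.9 FPKM, and SLC2A1, the glucose transporter GLUT1, from 27.4 ± 0.982 to 110.1 ± 15.4 FPKM. The genes that fell, named after their values were seen, were VEGFA, the angiogenic growth factor, and SLC2A3, another glucose transporter, with log2 differences of -2.29 and -0.94. The list median was 0.65 (adjusted p = 1.73e-04 by camera; adjusted p = 0.358 with an estimated correlation). Among 25 genes of the ATF4 and amino acid response, 2 rose (2 higher and 0 lower adjusted over the list alone): DDIT4, an inhibitor of mTOR signalling that also responds to hypoxia, from 24.9 ± 0.061 to 351 ± 68.8 FPKM (adjusted p = 0.00171), and SLC7A5, an amino acid transporter, from 11.7 ± 0.113 to 36.4 ± 6.77 FPKM (adjusted p = 0.0193). TRIB3 and STC2 had log2 differences of 0.99 ± 0.32 and -0.80 ± 0.27 (SE) and did not pass, nor did the list (median 0.34; adjusted p = 0.188 by camera; adjusted p = 0.599 with an estimated correlation). This list passed by camera with a preset correlation in the comparison of all 6 replicates, where its median was 1.08 (adjusted p = 0.00321 by camera and 0.847 with an estimated correlation). None of the 21 genes of the unfolded protein response changed (0 higher and 0 lower adjusted over the list alone; median 0.049; adjusted p = 0.771 by camera; adjusted p = 0.80 with an estimated correlation, with a downward direction). The smallest p-values were those of EIF2AK3, EDEM1, SDF2L1 and SEL1L, with log2 differences of -1.03 ± 0.35, -0.80 ± 0.36, 0.87 ± 0.54 and -0.38 ± 0.26 (SE).

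Of 19 HOX genes tested, which encode transcription factors of body patterning, 9 rose and none fell (13 higher and 0 lower adjusted over the list alone). HOXC10 rose from 0.0498 ± 0.0365 to 24.9 ± 6.32 FPKM, HOXC8 from 0.428 ± 0.0928 to 11.9 ± 2.92 FPKM, HOXC6 from 0.876 ± 0.123 to 11.6 ± 1.7 FPKM and HOXC4 from 0.801 ± 0.0165 to 13.3 ± 3.55 FPKM, each with an adjusted p of at most 0.00237. The list median was 0.99 (adjusted p = 1.34e-07 by camera; adjusted p = 0.308 with an estimated correlation). It was 1.51 with a pseudocount of 0.1, 2.86 with a mean of at least 5 FPKM and 0.61 with no filter on low values. Of 11 tested cancer-testis antigen genes, which are normally active in the germ line, 8 rose and none fell (9 higher and 0 lower adjusted over the list alone; median 1.82). SSX1 rose from 7.63 ± 0.991 to 112 ± 33.7 FPKM, MAGEA12 from 2.11 ± 0.117 to 42.5 ± 13.9 FPKM and CSAG1 from 4.86 ± 0.745 to 86.6 ± 45.6 FPKM. MAGEB2 was listed at 0 in control replicates 2 and 3 and at 10.8, 7.22 and 5.41 FPKM in the radioresistant replicates (adjusted p = 0.0027). Several of these genes have near-identical neighbours on the X chromosome, and their values are uncertain where reads could be split. With no filter the median of this list was 0.48. The list passed by camera (adjusted p = 2.16e-05; adjusted p = 0.308 with an estimated correlation).

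Of 12 stem-like and proneural glioma genes tested, 7 fell and 1 rose (3 higher and 7 lower adjusted over the list alone; median -1.52). ITGA6, the laminin receptor chain used as a marker of glioma stem cells, fell from 10.4 ± 0.814 to 0.133 ± 0.033 FPKM, SOX9 from 16.4 ± 0.824 to 1.12 ± 0.312 FPKM and the oncogene MYC from 14.1 ± 2.64 to 2.35 ± 1.04 FPKM (adjusted p = 8.34e-04, 0.00122 and 0.0144). SOX2, a transcription factor of neural stem cells, rose from 0.103 ± 0.065 to 9.45 ± 3.2 FPKM (adjusted p = 0.00237). The list passed by camera (adjusted p = 0.016; adjusted p = 0.308 with an estimated correlation), and not without radioresistant replicate 3 (adjusted p = 0.078), with the replicate number as a block (adjusted p = 0.0643) or without a filter on low values (adjusted p = 0.102, median 0.0071); over its alternatives the adjusted p ran from 0.0018 to 0.102. Of 17 Notch and Wnt pathway genes, 7 fell and 1 rose (1 higher and 8 lower adjusted over the list alone; median -0.74). DKK1 was at 16.5 and 20.9 FPKM in the controls and at 0.103, 0.0653 and 0 FPKM in the radioresistant replicates. WNT7B, a Wnt ligand, fell from 57.5 ± 0.33 to 6.94 ± 2.43 FPKM, the transcription factor gene TCF7 from 23 ± 2.33 to 3.84 ± 0.725 FPKM and RNF43, which removes Wnt receptors from the cell surface, from 2.52 ± 0.144 to 0.147 ± 0.0174 FPKM. Both ligands and inhibitors of Wnt signalling were thus among the genes that fell. The median was -0.40 without control replicate 3 and -0.17 with no filter on low values. The list passed by camera (adjusted p = 1.73e-04; adjusted p = 0.308 with an estimated correlation).

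Genes of the extracellular matrix changed in both directions. Of 23 matrix proteases and inhibitors, 9 fell and 1 rose (4 higher and 11 lower adjusted over the list alone; median -1.03; adjusted p = 3.94e-04 by camera; adjusted p = 0.409 with an estimated correlation). TIMP3 fell from 23.5 ± 0.665 to 0.213 ± 0.0718 FPKM, and the proteases ADAMTS5, MMP16 and ADAMTS12 fell, with log2 differences of -2.28, -2.01 and -1.73. The median of this list was -0.36 without radioresistant replicate 1 and -0.44 with no filter on low values. It was also -0.36 with the replicate number as a block, which takes its differences from the same replicates as the first of these. The list did not pass with all 6 replicates, where its median was above 0, at 0.20 (adjusted p = 0.239 by camera and 0.847 with an estimated correlation, with a downward direction). Of 25 matrix glycoproteins and integrins, 5 fell and 4 rose (5 higher and 10 lower adjusted over the list alone; median -0.63). LAMA4 fell from 41 ± 4.83 to 1.67 ± 0.631 FPKM, the integrin chain ITGB3 from 54.1 ± 6.21 to 10.3 ± 0.987 FPKM and VCAN, the proteoglycan versican, from 83.7 ± 4.08 to 20.8 ± 0.775 FPKM. ITGA11, a collagen receptor chain, was at 4.36 and 4.29 FPKM in the controls and at 0, 0.013 and 0.00849 FPKM in the radioresistant replicates. This list passed the set test (adjusted p = 0.0357 by camera; adjusted p = 0.594 with an estimated correlation), and lost the call without radioresistant replicate 1 (adjusted p = 0.191), after median-of-ratios scaling (adjusted p = 0.0552) and after quantile normalization (adjusted p = 0.0763), with a range of 4.48e-04 to 0.458 over its alternatives, and its median was -0.37 with no filter. Nor did it pass with all 6 replicates, where its median was above 0, at 0.27 (adjusted p = 0.953 by camera and 0.981 with an estimated correlation). Of 17 collagens, 3 fell and 1 rose (1 higher and 3 lower adjusted over the list alone). COL6A3 fell from 106 ± 10.7 to 7.27 ± 3.71 FPKM, COL8A1 from 9.59 ± 1.08 to 0.643 ± 0.264 FPKM and COL13A1 from 6.4 ± 0.799 to 0.431 ± 0.27 FPKM, and COL9A3 rose from 0.109 ± 0.00762 to 1.72 ± 0.251 FPKM. The median of the collagens was 0.48, their mean -0.037 and the direction of the set test downward (adjusted p = 0.464 by camera; adjusted p = 0.836 with an estimated correlation). The sign of the median depended on the replicate, at -0.64, 0.67 and 1.23 in radioresistant replicates 1, 2 and 3.

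Of 28 mesenchymal genes, 3 fell and 2 rose (2 higher and 3 lower adjusted over the list alone; median -0.15; adjusted p = 0.21 by camera; adjusted p = 0.469 with an estimated correlation). S100A4 rose as given above. CHI3L1, a secreted glycoprotein of the mesenchymal glioma profile, fell from 21.2 ± 1.59 to 2.57 ± 1.17 FPKM, the cadherin gene CDH11 from 29.3 ± 2.73 to 5.89 ± 2.32 FPKM and THBS1, thrombospondin 1, from 3.7 ± 0.38 to 0.0918 ± 0.0295 FPKM. Of 21 genes of the TGF-beta response, 3 rose and 5 fell (6 higher and 7 lower adjusted over the list alone). INHBA rose as given above and BMP4 rose from 0.137 ± 0.0171 to 3.5 ± 0.0981 FPKM. ID2, an inhibitor of differentiation, fell from 10.9 ± 0.741 to 1.27 ± 0.741 FPKM and TGFBR3, a TGF-beta co-receptor, from 3.92 ± 0.108 to 0.984 ± 0.139 FPKM. The median of this list was -0.36, its mean 0.029 and the direction of the set test downward (adjusted p = 0.253 by camera; adjusted p = 0.47 with an estimated correlation). Of 19 YAP/TAZ targets, 3 rose and 5 fell (4 higher and 7 lower adjusted over the list alone; median -0.57; adjusted p = 0.199 by camera; adjusted p = 0.469 with an estimated correlation). F3, tissue factor, rose from 3.01 ± 0.0582 to 30.7 ± 9.88 FPKM and the kinase gene NUAK2 from 1.01 ± 0.0875 to 6.69 ± 0.49 FPKM. DLC1 fell from 17.5 ± 1.63 to 3.97 ± 0.818 FPKM and FJX1 from 52.8 ± 2.67 to 18.8 ± 0.45 FPKM.

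Of 22 receptor tyrosine kinases and ligands, 6 fell and 2 rose (4 higher and 7 lower adjusted over the list alone; median -0.38). HGF fell as given above, IGFBP3, a binding protein of insulin-like growth factors, fell from 81.7 ± 7.47 to 6.21 ± 5.3 FPKM and EREG, a ligand of the EGF receptor, from 21 ± 5.57 to 3.4 ± 1.79 FPKM. PDGFA, a platelet-derived growth factor, rose from 3.26 ± 0.0265 to 14.9 ± 2.51 FPKM. The list passed the set test (adjusted p = 0.0425 by camera; adjusted p = 0.469 with an estimated correlation) and lost the call with a pseudocount of 0.1 (adjusted p = 0.0516), after median-of-ratios scaling (adjusted p = 0.0552) and after quantile normalization (adjusted p = 0.0737), with a range of 0.00131 to 0.0805 over its alternatives. Its median was -0.64 without radioresistant replicate 1, -0.60 without radioresistant replicate 2, -0.77 with a mean of at least 5 FPKM and -0.20 with no filter. In the comparison of all 6 replicates the list did not pass and its median was above 0, at 0.20 (adjusted p = 0.966 by camera and 0.981 with an estimated correlation, with a downward direction). Of 21 immediate-early and AP-1 genes, 3 rose and 8 fell (5 higher and 8 lower adjusted over the list alone; median -0.44; adjusted p = 0.124 by camera; adjusted p = 0.557 with an estimated correlation). Its medians in radioresistant replicates 1, 2 and 3 were 0.20, -0.46 and -0.46. JUNB, an AP-1 subunit, rose from 33 ± 0.661 to 149 ± 36.1 FPKM. DUSP4, a phosphatase that inactivates MAP kinases, fell from 31.4 ± 0.725 to 6.88 ± 1.96 FPKM, and ETV1 and ETV5, transcription factors induced by that pathway, from 18.3 ± 1.73 to 3.78 ± 1.21 FPKM and from 40.9 ± 2.02 to 12.6 ± 1.64 FPKM. The other 5 that fell, named after their values were seen, were the MAP kinase phosphatases DUSP5 and DUSP6, the receptor signalling inhibitors SPRY2 and SPRY4, and PHLDA1, with log2 differences of -1.66, -1.73, -2.67, -1.45 and -1.88.

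**Figure D3:**
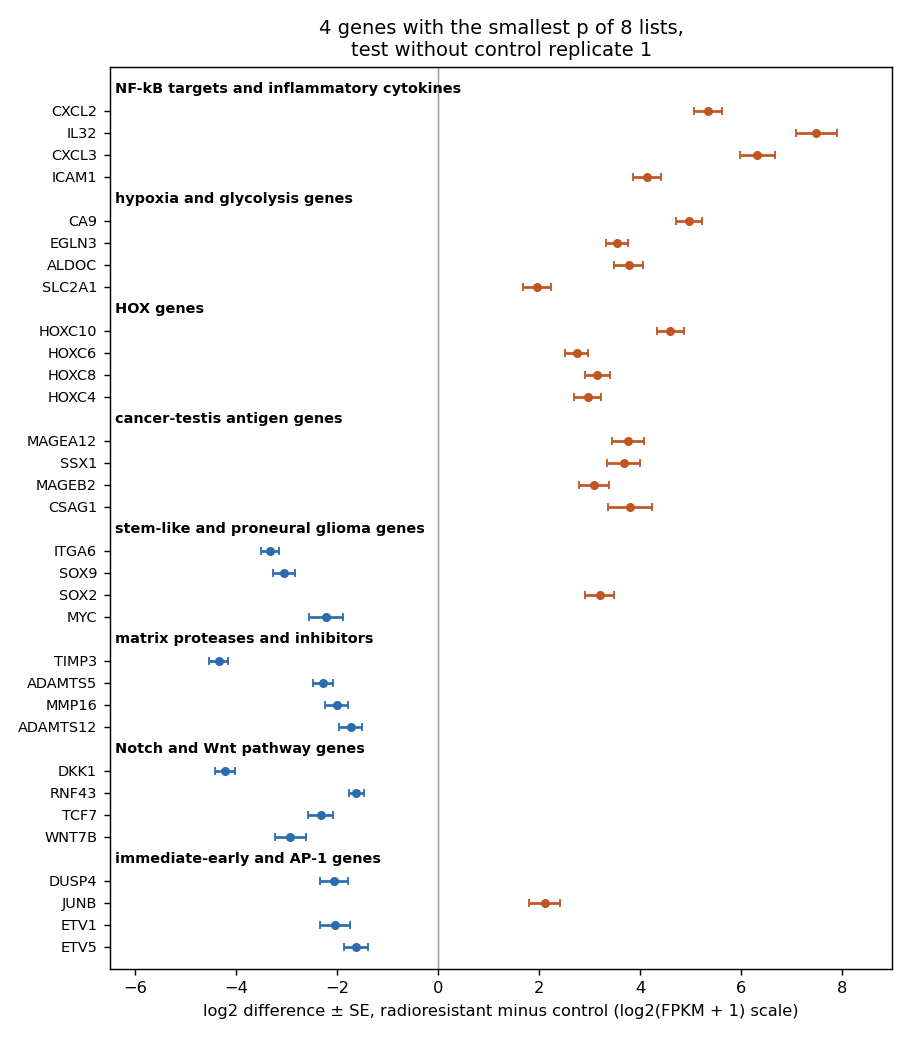
Log2 difference with its standard error, radioresistant replicates 1 to 3 minus control replicates 2 and 3, for the 4 members with the smallest p of 8 gene lists. The NF-kB, hypoxia, HOX and cancer-testis members shown lie above 0, from 1.96 for SLC2A1 to 7.49 for IL32; in the other 4 lists the members shown lie below 0 except SOX2 and JUNB.

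Of 29 p53 targets, 1 rose and none fell (0 higher and 0 lower adjusted over the list alone; median 0.11; adjusted p = 0.813 by camera; adjusted p = 0.833 with an estimated correlation). BBC3, the pro-apoptotic protein PUMA, rose from 3.18 ± 0.23 to 12.8 ± 5.1 FPKM (adjusted p = 0.0331). GADD45A, BTG2 and TIGAR had log2 differences of 1.33 ± 0.32, 0.77 ± 0.27 and -0.56 ± 0.21 (SE) and did not pass. Of 33 genes of DNA double-strand break repair, 1 fell and none rose (0 higher and 0 lower adjusted over the list alone; median -0.11; adjusted p = 0.188 by camera; adjusted p = 0.469 with an estimated correlation). FANCD2, a Fanconi anaemia protein, fell from 14.7 ± 0.32 to 6.56 ± 0.672 FPKM (adjusted p = 0.0358). The polymerase gene POLQ and the checkpoint kinase genes CHEK2 and ATR had log2 differences of -0.79 ± 0.22, 0.91 ± 0.27 and -1.10 ± 0.34 (SE) and did not pass. Of 30 genes of mitosis, 1 rose and none fell (0 higher and 0 lower adjusted over the list alone; median -0.18; adjusted p = 0.188 by camera; adjusted p = 0.652 with an estimated correlation). CENPF, a kinetochore protein, rose from 6.8 ± 0.882 to 22.5 ± 8.09 FPKM (adjusted p = 0.0428), and CCNA2, BUB1 and TTK had log2 differences of -1.18 ± 0.29, -1.06 ± 0.29 and -0.94 ± 0.43 (SE). None of 28 DNA replication genes changed (0 higher and 0 lower adjusted over the list alone; median -0.098; adjusted p = 0.242 by camera; adjusted p = 0.47 with an estimated correlation), and the helicase genes MCM6, MCM3 and MCM2 and the reductase gene RRM1 had log2 differences of -0.88 ± 0.24, -0.78 ± 0.25, -0.87 ± 0.33 and -0.61 ± 0.31 (SE). Of 20 apoptosis regulators, 1 fell (0 higher and 1 lower adjusted over the list alone; median 1.05e-05, mean 0.10; adjusted p = 0.902 by camera; adjusted p = 0.902 with an estimated correlation, with a downward direction), namely the death receptor gene TNFRSF21, from 44 ± 4.61 to 8.89 ± 1.3 FPKM. BCL2 had a log2 difference of -1.02 ± 0.27 (SE) and did not pass. BIK was listed at 0 in all control replicates and at 3.21, 0.98 and 0.966 FPKM in the radioresistant replicates, and did not pass (adjusted p = 0.0776).

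Among 30 NRF2 and antioxidant genes, 4 fell and none rose (0 higher and 4 lower adjusted over the list alone; median -0.12; adjusted p = 0.0716 by camera; adjusted p = 0.47 with an estimated correlation). All were aldo-keto reductases: AKR1C1 fell from 198 ± 25.2 to 15.3 ± 5.28 FPKM, AKR1C2 from 12.5 ± 1.55 to 2.42 ± 0.979 FPKM, AKR1C3 from 52.7 ± 1.27 to 14.3 ± 4.72 FPKM and AKR1B10 from 4.87 ± 0.00293 to 2.08 ± 0.22 FPKM. The AKR1C genes are close copies, and reads shared among them leave each single value uncertain. Of 16 drug transporters and detoxifying enzymes, 2 rose and 3 fell (3 higher and 5 lower adjusted over the list alone; median -0.35; adjusted p = 0.21 by camera; adjusted p = 0.47 with an estimated correlation). NNMT, nicotinamide N-methyltransferase, rose from 2.0 ± 0.0552 to 58.5 ± 53.2 FPKM. ALDH1A3, an aldehyde dehydrogenase used as a glioma stem cell marker, fell from 177 ± 15.5 to 48.3 ± 19.1 FPKM, ALDH3A2 from 33.3 ± 1.07 to 11.3 ± 1.9 FPKM and the transporter gene ABCG2 from 2.24 ± 0.35 to 0.754 ± 0.205 FPKM. Of 27 genes of cholesterol and lipid synthesis, 1 fell and none rose (0 higher and 0 lower adjusted over the list alone; median -0.47; adjusted p = 0.0254 by camera; adjusted p = 0.308 with an estimated correlation). The set call was lost with the replicate number as a block (adjusted p = 0.119, with a range of 0.00362 to 0.119 over its alternatives). It was also absent with all 6 replicates, where the median was -0.14 (adjusted p = 0.398 by camera and 0.86 with an estimated correlation). The gene that fell is among those not reported here. FADS1, a fatty acid desaturase, and DHCR7, a late enzyme of cholesterol synthesis, had log2 differences of 1.01 ± 0.26 and -1.42 ± 0.37 (SE) and did not pass.

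The 38 cytosolic ribosomal protein genes had a median log2 difference of 0.80 with no single gene past the threshold (0 higher and 0 lower adjusted over the list alone), and in 30 of them every radioresistant replicate lay above both controls. RPL11, RPLP2 and RPL4 had log2 differences of 1.26 ± 0.40, 1.31 ± 0.43 and 1.07 ± 0.36 (SE). The list medians of radioresistant replicates 1, 2 and 3 were 1.15, 0.36 and 0.81. The list passed the set test (adjusted p = 1.73e-04 by camera; adjusted p = 0.546 with an estimated correlation), and not with the replicate number as a block (adjusted p = 0.176) or after quantile normalization, where its median was 0.20 (adjusted p = 0.167; 1.46e-07 to 0.176 over all alternatives). None of 30 nuclear-encoded respiratory chain genes changed (0 higher and 0 lower adjusted over the list alone; median 0.12; adjusted p = 0.983 by camera; adjusted p = 0.99 with an estimated correlation, with a downward direction). By contrast, all 6 replicates gave a call by camera with a preset correlation, in the upward direction, and a median of 1.80 (adjusted p = 0.00253 by camera and 0.847 with an estimated correlation). The same 30 genes were tested, so the higher median comes from control replicate 1. Against control replicates 2 and 3, their medians were 0.32, -0.17 and 0.32 in radioresistant replicates 1, 2 and 3. NDUFS1, COX6C, SDHA and UQCRFS1 had log2 differences of -0.89 ± 0.26, 0.98 ± 0.32, -0.75 ± 0.28 and -0.62 ± 0.27 (SE). Of 19 replication-dependent histone genes, 1 fell (0 higher and 1 lower adjusted over the list alone; median -0.34; adjusted p = 0.0024 by camera; adjusted p = 0.47 with an estimated correlation). HIST1H2BJ fell from 14.1 ± 1.87 to 4.79 ± 0.521 FPKM, and HIST2H2BE, HIST1H2AC and HIST1H1C had log2 differences of -0.88 ± 0.21, -1.14 ± 0.37 and -1.16 ± 0.43 (SE). The median of the histone list was -0.60 without radioresistant replicate 1, -0.22 without radioresistant replicate 2 and -0.52 with a mean of at least 5 FPKM. It was also -0.60 with the replicate number as a block, which takes its differences from the same replicates as the first of these.

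In the planned comparison, with all 6 replicates, 13 lists passed by camera with a preset correlation. Other splits of the 6 replicates into 3 and 3 gave 9 to 15 lists, so this count does not set the real groups apart. The comparisons with and without control replicate 1 share 5 replicates, so a list that passes in both gains little support from that. The lists of NF-kB, interferon, hypoxia, HOX, cancer-testis, stem-like, Notch and Wnt, ribosomal protein and histone genes passed in both comparisons, with medians over all 6 replicates of 3.33, 0.77, 1.67, 0.77, 1.61, -1.18, -0.86, 1.65 and -1.41. All 6 replicates tested 22 stem-like and 25 Notch and Wnt genes, against 12 and 17 without control replicate 1. Genes that enter only through control replicate 1 tend to come out lower in the radioresistant group. Against control replicates 2 and 3, the 22 stem-like genes had medians of -0.038, 0.00055 and -0.023 in radioresistant replicates 1, 2 and 3. Their -1.18 thus rests on control replicate 1. The lists of MHC class I, the ATF4 response, the respiratory chain and leukocyte markers passed only with all 6 replicates, and those of matrix proteases, matrix glycoproteins, receptor tyrosine kinases and cholesterol synthesis only without control replicate 1. Among lists that passed in neither, medians that were below 0 without control replicate 1 were above 0 with all 6 replicates for double-strand break repair (0.11), mitosis (0.80), DNA replication (0.65), mesenchymal genes (1.08), the TGF-beta response (0.67), YAP/TAZ targets (0.49) and NRF2 genes (1.10). Control replicate 1 listed the 200 most abundant genes of control replicates 2 and 3 at a median ratio of 0.0705 to their mean. It thus raises the medians with all 6 replicates for lists of such genes.

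**Figure D4:**
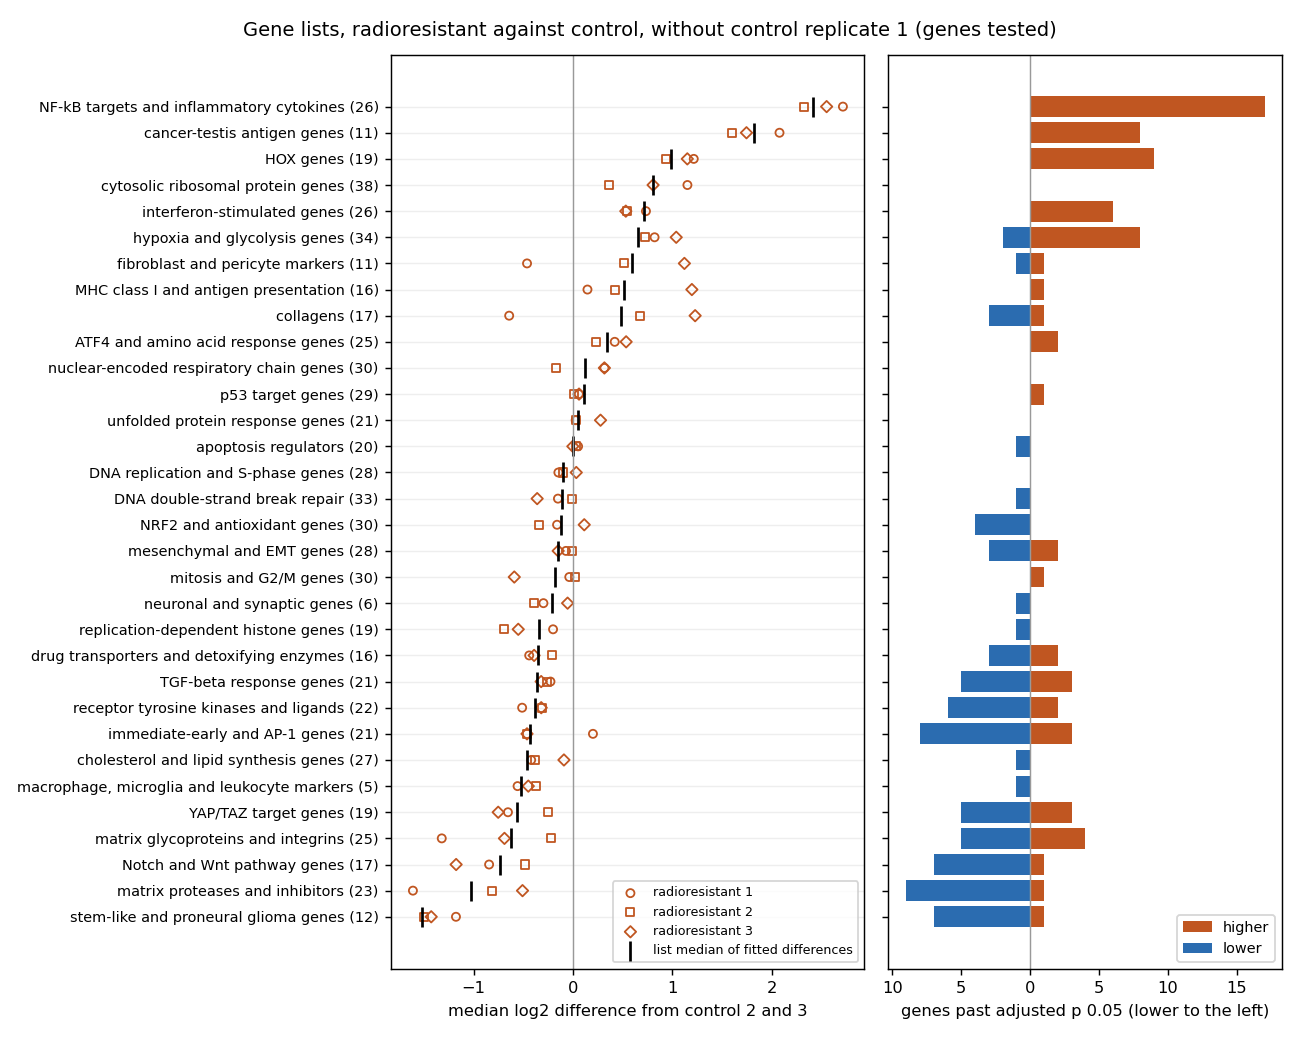
Left, median log2 difference of each gene list from control replicates 2 and 3 in each radioresistant replicate (open symbols) and over the fitted differences (bars), with the number of genes tested in brackets; right, the number of genes past an adjusted p of 0.05, higher to the right and lower to the left. The NF-kB list has the highest median, 2.41, and 17 higher genes; the stem-like list has the lowest, -1.52, with 7 lower genes and 1 higher.

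Genes of long interest in glioblastoma were read in all replicates. CDKN1A, the cell cycle inhibitor p21, was at 112 ± 2.49 FPKM in control replicates 2 and 3 and at 92 ± 20.4 FPKM in the radioresistant replicates. The ubiquitin ligase gene MDM2 was at 29.5 ± 0.61 and 29.4 ± 8.7 FPKM, EGFR at 16.7 ± 3.64 and 9.96 ± 2.29 FPKM, and the hyaluronan receptor gene CD44 at 278 ± 0.201 and 226 ± 61.9 FPKM. None of these 4 passed, and their adjusted p-values ran from 0.191 to 0.946. CDKN2A, the DNA repair gene MGMT and PROM1, the stem cell marker CD133, were listed at 0 in control replicates 2 and 3. In radioresistant replicates 1, 2 and 3, CDKN2A was at 0, 0.020 and 0.104 FPKM and PROM1 at 0.015, 0 and 0 FPKM, while MGMT was listed at 0 in each.

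Markers of other cell types were counted at 1 FPKM or more in each replicate. Of 17 endothelial markers, 1 reached 1 FPKM in each of the other 5 replicates, against 11 in control replicate 1. In control replicates 2 and 3 and radioresistant replicates 1, 2 and 3, the count was 5, 5, 3, 3 and 3 of 20 leukocyte markers, 6, 6, 5, 4 and 7 of 30 neuronal genes and 4, 4, 4, 5 and 5 of 16 astrocyte and oligodendrocyte markers, against 13, 22 and 9 in control replicate 1. Of 18 fibroblast and pericyte markers it was 9, 9, 10, 11 and 11, against 10 in control replicate 1. Among these, the collagen genes COL1A1 and COL1A2 and the smooth muscle actin gene ACTA2, named after their values were seen, were at 59.7 to 686, 44.4 to 301 and 13 to 41.2 FPKM over these 5 replicates. The endothelial marker ENG was at 31.3 ± 2.06 FPKM in control replicates 2 and 3 and at 54.1 ± 27.2 FPKM in the radioresistant cells, and did not pass (adjusted p = 0.387). Of 5 macrophage, microglia and leukocyte markers tested, 1 fell (1 higher and 2 lower adjusted over the list alone; median -0.53; adjusted p = 0.188 by camera; adjusted p = 0.469 with an estimated correlation): the MHC class II gene HLA-DRA, at 9.53 and 8.26 FPKM in the controls and at 0.171, 0.116 and 0 FPKM in the radioresistant replicates. TMEM119, CSF1R and CD74 had log2 differences of 0.94 ± 0.28, -0.53 ± 0.16 and -0.74 ± 0.37 (SE). When all 6 replicates were used, 12 of these markers were tested, and the list passed by camera with a preset correlation with a median of -1.44 (adjusted p = 0.011 by camera and 0.847 with an estimated correlation). Markers such as CD14 and SPI1 were at 50.7 and 30.1 FPKM in control replicate 1 and at no more than 0.608 and 0.596 FPKM elsewhere. They entered the test through control replicate 1 alone, so their fall was fixed in advance. Against control replicates 2 and 3, the medians of the 12 markers were -0.011, -0.015 and 0.0083 in radioresistant replicates 1, 2 and 3. Of 11 fibroblast and pericyte markers, 1 rose and 1 fell (1 higher and 1 lower adjusted over the list alone; median 0.59; adjusted p = 0.278 by camera; adjusted p = 0.705 with an estimated correlation), with medians of -0.46, 0.51 and 1.12 in radioresistant replicates 1, 2 and 3. THY1 rose from 1.43 ± 0.329 to 22.9 ± 14.4 FPKM and FAP fell from 8.9 ± 0.852 to 3.23 ± 1.2 FPKM. COL3A1, a fibroblast collagen, was at 0.261 ± 0.0649 FPKM in the controls and at 0.675, 4.37 and 4.43 FPKM in radioresistant replicates 1, 2 and 3 (adjusted p = 0.138). RGS5 had a log2 difference of 0.61 ± 0.18 (SE). Of 6 neuronal and synaptic genes, 1 fell, MAP2, from 2.94 ± 0.378 to 0.485 ± 0.20 FPKM (1 higher and 1 lower adjusted over the list alone; median -0.22; adjusted p = 0.344 by camera; adjusted p = 0.546 with an estimated correlation). NRXN2, GAP43 and TUBB3 had log2 differences of 1.68 ± 0.40, -0.51 ± 0.33 and -0.25 ± 0.28 (SE). Of 4 astrocyte and oligodendrocyte markers tested, too few for a test of the list, ALDOC rose as given above and GJA1, connexin 43, fell from 66.7 ± 3.41 to 12.6 ± 3.91 FPKM, and SLC1A3 and CNP had log2 differences of 0.12 ± 0.42 and -0.066 ± 0.28 (SE; 1 higher and 1 lower adjusted over the list alone).

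Replicates of a group were also compared with each other, with the technical replicates as error. Among the controls 15102 of 16069 genes differed, and 13233 of them by at least 1 on the log2 scale. Between control replicates 2 and 3, 5242 of 11440 genes differed, but only 4 by at least 1. Among the radioresistant replicates 11223 of 11927 genes differed, 4131 by at least 1. Replicate 3 stood apart: 284 genes differed by at least 1 between replicates 1 and 2, against 3456 between replicates 1 and 3 and 2695 between replicates 2 and 3. In replicate 3 the median of the MHC class I list was 0.87 above the mean of replicates 1 and 2, that of the collagens 0.94 above it, that of the fibroblast and pericyte markers 0.86 above it and that of the mitosis genes -0.64 relative to it. The difference of replicate 3 from the mean of replicates 1 and 2 rose with the GC content of transcripts (Spearman rho = 0.711 across 11357 genes, which are not independent replicates). The difference between radioresistant and control cells followed GC content with rho = 0.302 and transcript length with rho = -0.326 across the same genes. These tests take the technical replicates as error, so they measure differences between samples and not between conditions.

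Genes were last grouped by chromosome, with names matched to RefSeq genes of GRCh38, since the files use hg19. With all 6 replicates, the genes of 5 of 23 chromosomes moved together by camera with a preset correlation: higher on 16 and 19 and lower on 2, 4 and 6. This count was 0 without control replicate 2, without control replicate 3, without radioresistant replicate 3 and with an estimated correlation. Without control replicate 1 there were 9, with higher genes on 1, 11 and 19 and lower genes on 2, 3, 4, 5, 6 and 18. The largest medians were 0.49 on chromosome 19 and -0.29 on chromosome 2 (adjusted p = 2.94e-06 and 4.41e-06). On chromosome 19, 67 of 829 genes rose and 7 fell; on chromosome 2, 15 of 764 rose and 70 fell. No chromosome passed with an estimated correlation, a form of the test with few degrees of freedom here (adjusted p = 0.80 and 0.566 for these chromosomes). The estimated correlations of chromosomes 19 and 2 were 0.301 and 0.041, above the preset 0.01. If these estimates hold, the p-values with the preset correlation are too small. By fry no chromosome passed either. Its smallest adjusted p was 0.110 without control replicate 1 and 0.114 with all 6 replicates, and that of chromosome 19 without control replicate 1 was 0.241.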

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

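The scaling alternatives, the trend removals, the pairs of replicates and every alternative of the comparison without control replicate 1 were chosen only after the results were seen. With all 6 replicates, 6 genes changed; leaving out 1 replicate at a time gave 0 to 1224 genes, 0 to 656 higher, 0 to 568 lower, 0 to 1131 at least 2-fold, 13 to 18 lists and 0 to 9 chromosomes, and only control replicate 1 gave more than 0 genes when left out. The count of changed, higher and at least 2-fold genes was 2 with a pseudocount of 0.1, and 0 with no filter on low values (limma, 1368 genes at an unadjusted p under 0.05) and after quantile normalization (738). It was 4 after median-of-ratios scaling, 5 with a mean of at least 5 FPKM, 7 with the replicate number as a block, 3 against a fold change of 1.5 and 0 at an adjusted p under 0.01. Technical replicates taken as separate libraries gave 125 genes, all at least 2-fold, 99 higher and 26 lower. With an estimated correlation 0 lists and 0 chromosomes passed in both comparisons, and fry gave 3 lists with all 6 replicates and 13 without control replicate 1. These 13 differed from the 13 by camera without control replicate 1. Fry did not call ribosomal protein, histone and matrix glycoprotein genes (adjusted p = 0.132, 0.140 and 0.110). It called mesenchymal genes, drug transporters and leukocyte markers, each downward (adjusted p = 0.0185, 0.0244 and 0.00742), which camera did not.

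Without control replicate 1, leaving out a further replicate gave 256 to 4286 genes, 128 to 2306 higher, 126 to 1980 lower, 256 to 1808 at least 2-fold, 12 to 15 lists and 8 to 10 chromosomes; where 1 control replicate remained, it was assumed to vary like the radioresistant replicates. A mean of at least 5 FPKM gave 508 genes (274 higher, 234 lower, all at least 2-fold) among fewer genes tested, an adjusted p under 0.01 gave 419 and a fold change of 1.5 gave 482. The lower genes numbered 863 with no filter and 875 after removal of the GC and length trends; separate libraries gave 2405 genes, 1359 higher and 1046 lower. The block gave 1388 genes, 872 higher and 516 lower, 904 of them shared. Its differences come from replicates 2 and 3 of each group, as without radioresistant replicate 1, so the 2 are not separate alternatives. Deviations of replicates with the same number correlated at -0.00458, -0.238 and 0.0528 across genes. They were taken from group means that held control replicate 1, which stood far from the others, so they cannot show whether the numbers pair. The median of all genes was 0.095, 0.026 after median-of-ratios scaling and -0.013 after quantile normalization. Of 93 named genes past the threshold, 83 kept it under every alternative except a further replicate left out or the block, and 48 under all. Many were named for large changes or small p-values in these data, so they do not stand for all called genes. Of all 1224 called genes, 985 kept the call with no filter and 992 with separate libraries. With a mean of at least 5 FPKM, 508 of the 675 still tested kept it. Of named genes that had not passed, the sign changed with a further replicate left out for SLC1A3 (-0.17 to 0.50), CNP (-0.22 to 0.060) and MDM2 (-0.24 to 0.18), given as log2 differences. SLC1A3 was at -0.17 with the block, and MDM2 at 0.077 without the length trend and 0.12 without the GC and length trends. Of list calls, those of matrix glycoproteins and of receptor tyrosine kinases also ended without the length trend (adjusted p = 0.061 and 0.0649) and without the GC and length trends (0.0716 and 0.0805), and those of matrix glycoproteins, stem-like, cholesterol and ribosomal protein genes with the block (0.458, 0.0643, 0.119 and 0.176). Control replicates 2 and 3 alone differed in 5242 genes. The cause of these changes was not tested. Alternatives that need counts (TMM, size factors, upper quartile, DESeq2, voom and a CPM filter) were not run, since the files hold FPKM, and lists and chromosomes were not run with technical replicates as separate libraries. FPKM gives no counts, so depth limits the low values by an unknown amount.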

Other observations

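The counts and groups of this paragraph and the next with their checks, the tests of admixture, of another source of RNA and of misplaced gene names for control replicate 1, and the quantile normalization read beside the scaling tests were chosen only after the results were seen. Without control replicate 1, 46 genes had at least 5 FPKM in all 3 radioresistant replicates and less than 0.5 FPKM in control replicates 2 and 3, and 25 genes had the reverse pattern. The former held VCAM1, an adhesion molecule for leukocytes, which was listed at 0 in control replicates 2 and 3 and was at 5.62, 10.1 and 10.9 FPKM in the radioresistant replicates (limma adjusted p = 0.00254), TMEM173, the innate immune sensor STING, which rose from 0.204 ± 0.048 to 11.8 ± 5.86 FPKM (SD, n = 2 and 3; limma adjusted p = 0.00547), and the tubulin gene TUBB4A, which rose from 0.0242 ± 0.0233 to 6.86 ± 2.87 FPKM (adjusted p = 0.00433). The latter held TLR4, a receptor of innate immunity, which fell from 9.99 ± 1.5 to 0.327 ± 0.116 FPKM (adjusted p = 8.82e-04), THBS2, thrombospondin 2, which fell from 5.9 ± 0.182 to 0.212 ± 0.0359 FPKM (adjusted p = 8.91e-04), and the transcription factor gene SALL1, which fell from 7.27 ± 0.701 to 0.0231 ± 0.0131 FPKM (adjusted p = 8.34e-04).

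Genes were also grouped by the letters that open their names, 211 groups in all. Of 86 long intergenic non-coding RNA genes named LINC, 22 rose and 2 fell, and of 147 genes known by a provisional LOC name, 26 rose and 3 fell (Fisher's exact test for higher genes, adjusted p = 3.34e-07 and 2.09e-05). The filter on the mean over 3 radioresistant and 2 control replicates admits a low gene more easily where the radioresistant group is the higher. Neither group passed with no filter (adjusted p = 0.145 and 1.0), with the filter on control replicates 2 and 3 alone (0.0649 and 0.317) or by camera with an estimated correlation (0.972 for each), though both passed with the filter on either group (6.81e-10 and 2.13e-05). The shares that rose thus depend on the filter and on the test.

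Control replicate 1 stood apart from every other replicate. Control replicate 2, thinned to its estimated depth in a simulation, still correlated with control replicate 3 at r = 0.996, against 0.233 for control replicate 1 over the same genes, which argues with the levels of CDKN2A and MTAP against low depth alone. Over the 200 most abundant genes of control replicates 2 and 3 its median ratio to their mean was 0.0705, which argues against U87MG RNA with a minor admixture. RNA of another source than U87MG stays open: the levels of CDKN2A and MTAP in its 3 libraries, 5.62 FPKM or more, prompted this explanation and so cannot test it, and no biological explanation was tested. Ribosomal protein genes were among the top 5% of genes in 92.1% of 38 cases in control replicate 1 and 100% in control replicate 2, so gene names were not misplaced as a whole.

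The cytosolic ribosomal protein genes were higher in the radioresistant replicates without control replicate 1. After removal of each replicate's trend with transcript length their median was 0.78 (quartiles 0.51 and 0.94), which argues against that trend as the whole cause. After median-of-ratios scaling it was 0.73, above the bound of 0.6 set in advance against scaling, but after quantile normalization, also a scaling, it was 0.20, so that the bound did not cover every scaling. A scaling difference between libraries and a difference between the cells cannot be told apart here, and the latter, including radiation and growth in mice, was not tested.

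Genes of 9 chromosomes moved together without control replicate 1. After removal of the trends with transcript GC content and length 8 chromosomes passed, which argues against these trends as the whole cause. After median-of-ratios scaling 9 passed, where 1 factor per library moves all chromosomes nearly alike and so decides little. After quantile normalization 9 passed too. It moves genes by their level and not by their chromosome, so neither result decides on scaling. Gains or losses of chromosomes in the radioresistant cells may account for the pattern, as a hypothesis only, since DNA was not analysed here. Moreover, 0 chromosomes passed with an estimated correlation or by fry.

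The 6 replicates form 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 6 changed genes, 6 higher, 0 lower and 6 at least 2-fold, and the highest other split gave 0 of each. Thus 1 split reached the count of changed, higher and 2-fold genes, and all 10 reached the 0 lower genes, where 883 genes had an unadjusted p under 0.05 by limma. The real split gave 13 lists and 5 chromosomes, against 9 to 15 lists and 0 to 4 chromosomes in the others. The count of lists was reached by 7 splits and that of chromosomes by 1.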
